A study of Homo sapiens with 8 samples.

How the data were processed

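The series holds ATAC-seq of NCI-H295R, an established human adrenocortical carcinoma cell line. ATAC-seq maps open chromatin by the places where the transposase Tn5 inserts sequencing adapters. The 8 libraries fall into 4 groups of 2, which the labels call biological replicates: vehicle (DMSO), the EZH2 inhibitor EPZ-6438 (EZH2i, 62 µM), the CBP inhibitor PRI-724 (CBPi, 26 µM), and forskolin (FSK, 10 µM). Cells were exposed for 96 h to vehicle, EZH2i or CBPi, the last 2 at doses the labels give as IC-50 doses. The forskolin cells had 48 h of vehicle and then 48 h of forskolin.

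The files are 4 peak lists, 1 per group, on build hg38 per the submitters' processing notes, which name Bowtie2, Genrich and deepTools 2.0 without their roles or settings. How the 2 libraries of a group were combined, how reads were filtered, whether read ends were shifted for the Tn5 insertion, and the peak threshold are not given in the sources used here. Each list therefore carries no spread between replicates, and no read counts or depths were used for any library, so depth is unknown. Every peak has the authors' signal, deposited as the area of significance under the peak, whose smallest value was 200.0 in each list. The deposited score agreed within 1 with 1000 times area divided by width, capped at 1000, for 100.0% of peaks. The deposited −log10 of the summit p ranged from 2.72 to 15.9 in the vehicle list. The area was used only within a list, to rank peaks, to shorten the list, to form area bins and, divided by width, to compare gained peaks inside and outside a set of windows, since areas of lists from libraries of unknown depth cannot be set against each other.

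All peaks lay on chromosomes 1 to 22 and X. A vehicle peak was kept when at least 1 bp of it was covered by a peak of the treated list, and otherwise lost; a treated-list peak with no vehicle peak under it was gained. Both words describe the lists: a peak can leave a list because it falls just under the caller's threshold. Shares carry Wilson 95% intervals, which treat peaks as independent and cover counting error only. No p-value across peaks or genes was computed, because each group is a single list.

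Gene coordinates came from a RefSeq table of assembly GRCh38.p14, whose coordinates are those of hg38, with 19974 protein-coding genes on these chromosomes. All 299 genes of the fixed lists matched. The table gives no strand, so the transcription start was not known; the planned promoter class was replaced by a gene-end class, peaks within 1 kb of either annotated end of a protein-coding gene, and other peaks are called distal. Gene-end peaks therefore include transcript 3′ ends as well as promoters. A gene lost or gained its gene-end peak when 1 of the lists had a peak within 1 kb of an end and the other had none, which includes peaks whose border moved. Of the genes counted as losing one, 589 of 622 (EZH2i), 296 of 318 (CBPi) and 631 of 667 (FSK) had a lost peak there, and of those counted as gaining one, 121 of 135, 231 of 258 and 160 of 187 had a gained peak. A peak was assigned to the protein-coding gene with the nearest end within 100 kb of the summit. No exon, intron or UTR annotation was used beyond whether a summit lay between the ends of a gene. No genome sequence was used, so the planned search for 23 motifs and any correction for GC content were not run.

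For each of 13 gene lists fixed before the data were examined, the share of assigned vehicle peaks that were kept was compared with the share expected from the 20 area bins of the vehicle list. The difference was placed among 10000 random gene lists of the same size matched on peaks per gene; a list is described as outside the random range below percentile 2.5 or above 97.5. With 39 combinations of list and treatment, 1.95 would fall outside by chance at that rate. The percentile describes these lists and is not a p-value. Gained peaks, as a share of the treated list's peaks, were placed among random gene lists matched on the treated list's peaks per gene. That share had no expectation from peak area or class. Differences between treatments in the kept share beyond expectation were placed among the random lists used for kept peaks. Both comparisons were added after seeing the data. The lists hold adrenocortical steroidogenic genes, Wnt/β-catenin targets, cAMP/PKA/CREM targets, developmental transcription factors chosen as Polycomb targets, and Polycomb and coactivator genes. They also hold cell cycle and E2F genes, p53 and stress genes, cholesterol supply genes, housekeeping genes, and markers of fibroblasts, endothelium, immune cells and chromaffin cells.

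Named peaks and genes followed a rule fixed at the same time: per treatment, the 6 lost and the 6 gained peaks of largest area; the 4 genes with the most lost peaks above expectation and the 4 with the most gained; up to 4 members of each list, first those whose gene-end peak was lost or gained and then those with the largest excess of lost or gained peaks; and always EZH2, CREBBP, CTNNB1 and NR5A1. CYP21A2 has a near-identical pseudogene copy, so reads there may be misplaced and its values are uncertain. Of the genes the rule selects as list members, the text gives values for some only, picked after their values were seen, and 1 gene is not reported here.

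The 3 treatments share the vehicle list, which cannot be split. For the overlap of lost peaks, the number expected from independent lists and the mean of 1000 simulations, in which each treatment loses vehicle peaks at its own rate per area decile, are given beside the observed number. The same was done for gained peaks after seeing the data, over the peaks of both treated lists joined where they overlap; neither value stands for an unchanged group, which was not simulated. Alternatives were a minimum overlap of 50%, overlap of the summit, the larger-area 50% of each list, lists of equal length, merging of peaks within 500 bp, a gene-end window of 2 kb, assignment within 50 kb or to the gene whose body holds the summit, and others given in the closing section.

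The code was tested on simulated lists made from the vehicle list with known losses and gains, whose counts it returned exactly. For 200 genes given an added loss, the true list differences of -12.6, -12.6 and -12.7 points in the EZH2i, CBPi and FSK simulations were returned as -16.1, -13.1 and -12.9. With a loss of 15 points added to 200 genes, 97 of 100 lists of 22 such genes fell below the random range in the EZH2i simulation, and 86 in the CBPi and in the FSK simulations, each over 15792 genes. Of 100 unchanged lists, 10, 7 and 9 fell outside the range in the EZH2i, CBPi and FSK simulations, so the range is somewhat narrower than its nominal level. Analyses used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.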

Results

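Open chromatin of NCI-H295R adrenocortical carcinoma cells was compared between vehicle and 3 treatments: the EZH2 inhibitor EPZ-6438 (EZH2i), the CBP inhibitor PRI-724 (CBPi) and forskolin (FSK), an activator of adenylyl cyclase that raises cAMP. EZH2 is the histone H3 lysine 27 methyltransferase of Polycomb repressive complex 2, and CBP is a histone acetyltransferase and coactivator. Histone marks were not measured here, nor which function of CBP the drug affected. Each group had 2 libraries and 1 deposited peak list, so no value below has a replicate error, and read depth is unknown. The vehicle list held 61016 peaks over 42.73 Mb, the EZH2i list 41086 peaks over 31.5 Mb, the CBPi list 47161 peaks over 36.68 Mb and the FSK list 51095 peaks over 35.74 Mb. Gene-end peaks made up 22.11% of the vehicle list (95% interval 21.78 to 22.44), 30.62% of the EZH2i list, 28.03% of the CBPi list and 25.26% of the FSK list.

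**Figure D1:**
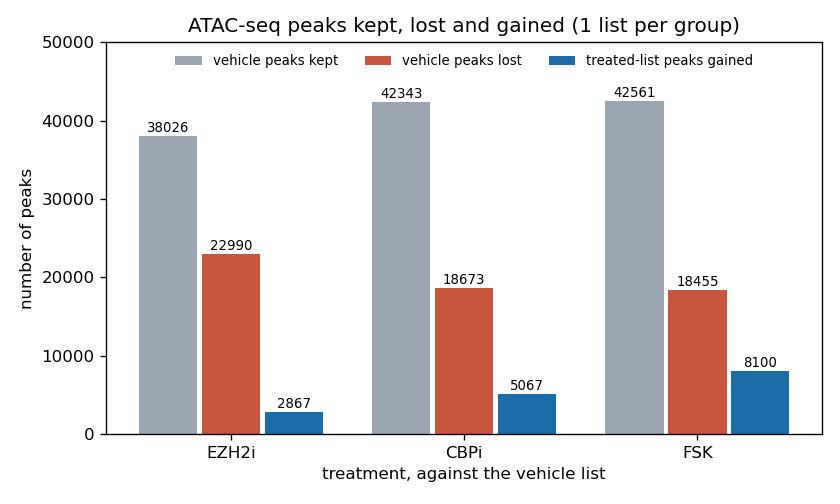
Bars give the number of vehicle peaks kept (grey) and lost (red) and of treated-list peaks gained (blue) for each treatment on the horizontal axis, each from 1 peak list per group, without error bars. Lost peaks outnumbered gained peaks with each treatment, by 22990 to 2867 with EZH2i, 18673 to 5067 with CBPi and 18455 to 8100 with FSK, in lists of unequal length.

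The first comparison asked how EZH2 inhibition altered open chromatin. With EZH2i, 22990 of the 61016 vehicle peaks were lost (37.68%, 95% interval 37.29 to 38.06), and 2867 peaks were gained, 6.978% of the EZH2i list (6.736 to 7.228). Distal peaks accounted for most of the loss: 54.16% of distal vehicle peaks were kept (53.71 to 54.61) against 91.06% of gene-end peaks (90.57 to 91.53). Of 13509 genes with a vehicle peak at a gene end, 622 had none in the EZH2i list, and 135 genes acquired one. Among gained peaks, 9.313% were gene-end peaks (8.303 to 10.43). The lost peaks were mostly small: 2326 of them were among the 30508 vehicle peaks of larger area, and 1 was in the top decile of area. Within area deciles the difference in share kept between gene-end and distal peaks averaged 11.4 points, against 36.9 without that matching, and with all lists cut to the same 41086 peaks of largest area 7289 vehicle peaks were lost.

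The lost peak of largest area with EZH2i lay on chromosome 13 at 89659066 to 89661084 (hg38), with no protein-coding gene end within 100 kb; 8.54% of vehicle peaks had a larger area. A neighbouring pair inside CEP112 on chromosome 17, at 65968986 to 65970343 and 65970469 to 65971877, was lost with EZH2i, as were peaks inside SPATA16 (chromosome 3, 172968083 to 172969437) and PDZRN4 (chromosome 12, 41220589 to 41222239). A peak 35147 bp from SERBP1 on chromosome 1 (67464469 to 67465896) completed the 6. The gained peak of largest area covered 7764 bp inside LZTR1 on chromosome 22 (20991216 to 20998979). Others lay inside C13orf46 on chromosome 13 (113928137 to 113931686 and 113968836 to 113974194), RASA3 on the same chromosome (113996124 to 113998941), DGKQ on chromosome 4 (961825 to 967344) and EGFL7 on chromosome 9 (136658192 to 136663715). The 6 gained peaks all overlapped peaks of the CBPi and FSK lists. Counted per gene, losses above expectation were largest at LRRK2 (9 of 11 peaks lost, 4.19 expected), BEND5 (10 of 13, 5.31 expected), PDZRN3 (10 of 19, 5.4 expected) and GALNT10 (11 of 16, 6.46 expected). RASA3 gained 39 peaks, TNS3 34, COBL 28 and IKZF1 21.

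None of the 13 gene lists left the random range with EZH2i. Among adrenocortical steroidogenic genes 67 of 103 vehicle peaks were kept (65.0%, 66.2% expected, percentile 33.44), and 17 of 18 genes kept their gene-end peak. The exception was MC2R, the ACTH receptor gene, where both assigned peaks were lost, with 1.58 expected. SCARB1, which encodes the HDL receptor, lost 10 of 23 peaks with 8.03 expected, and CYP11A1, the side-chain cleavage enzyme gene, lost 2 of 6 and gained 1. Wnt targets kept 86 of 121 peaks (71.1%, 66.3% expected, percentile 90.23); all 19 gene-end peaks were kept and NOTUM, a secreted Wnt inhibitor gene, gained a gene-end peak. LGR5 lost 7 of 10 peaks with 5.33 expected. The cAMP targets kept 80 of 116 (69.0%, 68.8% expected, percentile 54.83), with gene-end peaks lost at SGK1 and PDE4D.

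Developmental transcription factor genes, listed as Polycomb targets, kept 126 of 178 peaks with EZH2i (70.8%, 64.3% expected, percentile 93.38). Whether Polycomb controls these genes in NCI-H295R cells was not measured. Of 43 with a vehicle gene-end peak, 40 kept it and NEUROD1, HOXD10 and HOXA9 lost it. Those 3 peaks were small, with vehicle areas of 380.9, 270.8 and 216.0 against a vehicle-list median of 581.4. HOXD10 and HOXA9 each lost their 1 assigned peak, with 0.8 and 0.88 expected, and HOXD10 lost it with all 3 treatments. Of the 60 genes 0 gained a gene-end peak. Only those without one could, and over all 19974 genes 135 did, so that 0 says little about Polycomb targets. The gene list gained 8 peaks, 6.02% of its 133 EZH2i peaks (3.08 to 11.4), including 2 at MSX2. Polycomb and coactivator genes kept 65 of 102 (63.7%, 68.6% expected, percentile 10.33) and all 24 gene-end peaks, among them those of EZH2, CREBBP and CTNNB1; AEBP2 lost 11 of 19 peaks with 7.42 expected. NR5A1, the gene of the steroidogenic regulator SF1, kept its 3 peaks. Cell cycle genes kept 44 of 63 (69.8%, 73.5% expected, percentile 14.06) and all 29 gene ends. The p53 and stress list kept 47 of 58 (81.0%, 77.2% expected, percentile 68.05), and BBC3, which encodes the apoptosis activator PUMA, had a peak within 1 kb of its end where the vehicle list had none, though that peak overlapped a vehicle peak. Cholesterol supply genes kept 49 of 75 (65.3%, 67.0% expected, percentile 34.41), DHCR7 losing 4 of 5, and housekeeping genes 46 of 60 (76.7%, 69.8% expected, percentile 88.56). Of the marker lists for other cell types, fibroblast genes kept 25 of 43 peaks (percentile 44.99), endothelial genes 13 of 28 (percentile 25.68), chromaffin genes 17 of 25 (percentile 67.66) and immune genes 38 of 46 (percentile 96.17). IKZF1 held 37 of those 46 immune-list peaks.

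**Figure D2:**
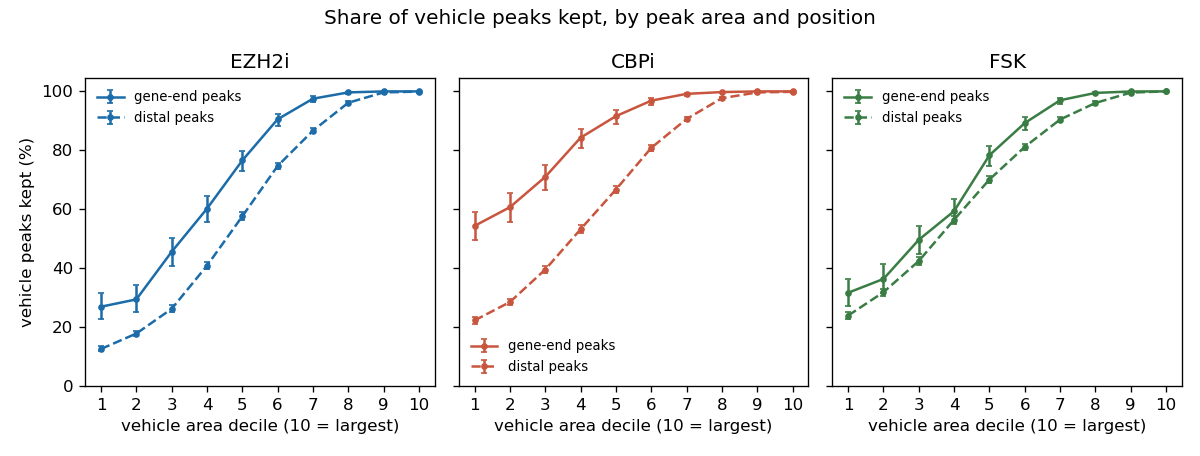
The share of vehicle peaks kept (vertical axis, percent) is plotted against the decile of vehicle peak area (horizontal axis) for gene-end peaks (solid) and distal peaks (dashed), with Wilson 95% intervals as bars. In the lowest decile 54.36% of gene-end and 22.28% of distal peaks were kept with CBPi, against 31.67% and 23.94% with FSK and 26.93% and 12.59% with EZH2i.

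The second comparison concerned CBP inhibition. With CBPi, 18673 vehicle peaks were lost (30.6%, 30.24 to 30.97) and 5067 were gained, 10.74% of the CBPi list (10.47 to 11.03). Gene-end peaks were kept at 95.49% (95.12 to 95.82) and distal peaks at 61.99% (61.55 to 62.43). Gene-end peaks disappeared at 318 genes and appeared at 258. Matched on area decile, the gene-end share exceeded the distal share by 17.9 points, against 33.5 unmatched. Distal peaks in the fifth of 5 Mb windows with the most genes were kept at 77.4% and those in the fifth with the fewest at 47.5%, a split chosen after seeing the data; in the same windows the EZH2i list kept 61.5% and 49.6% and the FSK list 65.3% and 66.3%. Of the 30508 vehicle peaks of larger area 1663 were lost, and when all lists held 41086 peaks 7415 were lost.

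The largest peak lost with CBPi stood on chromosome 12 at 29790303 to 29794632, 7782 bp from the end of TMTC1, and only 0.244% of vehicle peaks had a larger area. The EZH2i and FSK lists both held a peak there. A peak at chromosome 18, 39800816 to 39803354, with no gene end within 100 kb, was exceeded in area by 4.18% of vehicle peaks; both other treated lists retained it. Further losses lay inside ZNF385D (chromosome 3, 21617023 to 21618027), inside CEP112 (chromosome 17, 65970469 to 65971877), 13249 bp from EIF3H (chromosome 8, 116628532 to 116629828) and on chromosome 5 at 25758915 to 25760435. Gained peaks of largest area lay 4088 bp from ARHGEF2 (chromosome 1, 155983023 to 155984186), 11891 bp from DNAJB12 (chromosome 10, 72320466 to 72321388), inside CAMK2B (chromosome 7, 44219418 to 44221825), inside C13orf46 (chromosome 13, 113928324 to 113931019), 172 bp from CHCHD10 and inside C22orf15 (chromosome 22, 23764085 to 23766532) and 2808 bp from LARP6 inside LRRC49 (chromosome 15, 70856664 to 70857428). Each of these gained peaks except that inside LRRC49 overlapped peaks of both the EZH2i and FSK lists. The gained peak inside LRRC49 overlapped a peak of the EZH2i list only. VWC2 lost 18 of 25 peaks with 10.9 expected, PDZRN4 13 of 20 with 7.6, ABCA13 17 of 27 with 11.73 and MCTP2 8 of 15 with 3.34. VWC2 and ABCA13 both lie on chromosome 7 at 45 to 50 Mb. Of the 473 vehicle peaks in that window 198 were lost with CBPi, 112 with EZH2i and 105 with FSK. Whether the losses at these genes are particular to them was not tested. Gains were most numerous at RASA3 (36), TNS3 (22), RAMP3 (15) and CAMK2B (14).

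**Figure D3:**
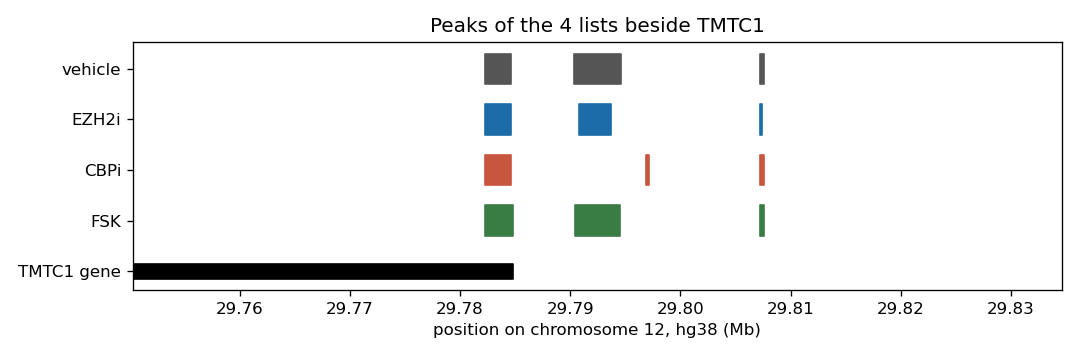
Bars mark the extent of each peak of the 4 lists along chromosome 12 (horizontal axis, hg38, Mb), with the end of the TMTC1 gene in black. The peak at 29790303 to 29794632 of the vehicle list has a counterpart in the EZH2i and FSK lists and none in the CBPi list, while the peak at the gene end is in all 4.

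Wnt targets kept more peaks with CBPi than their areas predicted. Of their 121 vehicle peaks 104 were kept (86.0%, 78.6 to 91.0), against 72.6% expected, an excess of 13.3 points at percentile 99.57. All 19 gene-end peaks were kept, NOTUM gained one, AFF3 and NKD1 gained 2 peaks each and APCDD1 gained 1. Gains near Wnt targets made up 10 of 111 CBPi peaks (9.01%, 4.97 to 15.8), inside the random range at percentile 19.75. Housekeeping genes kept 55 of 60 (91.7%, 75.8% expected, percentile 98.65), though with lists of equal length the excess was 3.84 points against 15.9. Developmental transcription factor genes kept 146 of 178 (82.0%, 71.2% expected, percentile 98.94). That list came inside the random range, at percentile 93.8, when expectation was also taken by the gene content of 5 Mb windows, and its excess of 10.9 points was 7.84 without TBX3 and 0.424 in the larger-area 50% of both lists. Only HOXD10 in it lost its gene-end peak, EVX1 gained one, and PAX9 and FOXA2 lost 3 of 5 and 2 of 3 peaks.

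Steroidogenic genes kept 82 of 103 peaks with CBPi (79.6%, 72.6% expected, percentile 80.43), MC2R again losing both of its peaks, with 1.33 expected, including the gene-end peak, while SCARB1 lost 8 of 23 and SOAT1, encoding a cholesterol esterifying enzyme, gained 2. The cAMP targets kept 89 of 116 (76.7%, 74.8% expected, percentile 47.51), with gene-end peaks lost at SGK1 and PDE4D and 2 peaks gained each at ATF3 and KLF4. Gains near p53 and stress genes made up 12 of 61 CBPi peaks (19.7%, 11.6 to 31.3), percentile 97.84 of random lists, with 3 at TRIB3 and 2 at BBC3. Without TRIB3 the share was 16.1%, under the 19.4% that bounds the random range. This share was not adjusted for peak area or class. That list kept 50 of 58 vehicle peaks (percentile 48.68). Polycomb and coactivator genes kept 83 of 102 (percentile 80.22) and all 24 gene ends, PHF19 gaining a gene-end peak; EZH2 kept 3 of 5 peaks, CREBBP 3 of 4, and CTNNB1 and NR5A1 3 of 3 each. Cell cycle genes kept 55 of 63 (percentile 82.59) and cholesterol supply genes 60 of 75 (percentile 75.48), with 2 gained peaks each at LSS and NPC1. Markers of other cell types stayed inside the range by peak area: fibroblast 32 of 43 (percentile 77.19), endothelial 19 of 28 (percentile 78.0), immune 31 of 46 (percentile 64.93) and chromaffin 18 of 25 (percentile 33.76). When expectation was also taken by gene content, fibroblast genes were outside it, 13.3 points above expectation (percentile 97.57), but by area alone the value was -3.0 in the larger-area 50% of both lists, 3.14 with lists of equal length and 2.87 by gene body.

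The third comparison addressed cAMP signalling through forskolin. With FSK, 18455 vehicle peaks were lost (30.25%, 29.88 to 30.61) and 8100 were gained, 15.85% of the FSK list (15.54 to 16.17). The share kept was 91.43% for gene-end peaks (90.95 to 91.89) and 63.6% for distal peaks (63.17 to 64.03). Gene-end peaks were lost at 667 genes and gained at 187, and 4.963% of gained peaks were gene-end peaks (4.511 to 5.458). Of the gained peaks 941 were in the larger-area 50% of the FSK list (11.62% of its gains), against 214 for EZH2i (7.464%) and 243 for CBPi (4.796%) in their own lists. At equal area decile the gene-end excess was 4.9 points, against 27.8 unmatched. Of the 30508 vehicle peaks of larger area 1803 were lost, and when all lists held 41086 peaks 8501 were lost.

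Forskolin gained its peak of largest area on chromosome 10 at 110511903 to 110513206, 1328 bp from an end of DUSP5, which encodes an ERK phosphatase; 8.12% of FSK peaks had a larger area. The next lay inside LRRC27 (chromosome 10, 132363210 to 132365713), where neither inhibitor list had a peak. MCPH1 gained a peak 782 bp from its end (chromosome 8, 6648694 to 6649607), likewise absent from both inhibitor lists. The remaining 3 were on chromosome 10 at 128629252 to 128630027, inside C13orf46 (chromosome 13, 113928174 to 113930693) and inside PTPRN2 (chromosome 7, 157932293 to 157933173). Those 3 and the peak near DUSP5 overlapped peaks of both inhibitor lists, so they were not particular to FSK. The 6 largest lost peaks all had a counterpart with both inhibitors. They were on chromosome 3 at 73818274 to 73819759, chromosome 7 at 25407979 to 25409173, inside GABBR2 (chromosome 9, 98671598 to 98673203), inside ARL15 (chromosome 5, 53934186 to 53935684), inside SYNE1 (chromosome 6, 152350385 to 152351539) and on chromosome 5 at 88439232 to 88440552. PALM2AKAP2 lost 10 of 13 peaks with 5.34 expected, NRCAM 8 of 12 with 3.89, GLCE 7 of 10 with 2.94 and PLAGL1 7 of 11 with 3.09. COBL and RASA3 gained 32 each, TNS3 30 and GRB10 28.

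Wnt targets lost more peaks with FSK than their areas predicted. Of 121 vehicle peaks 72 were kept (59.5%, 50.6 to 67.8), against 73.1% expected, a difference of -13.6 points at percentile 0.01. The gene-end peaks of SP5 and CCND1 were lost, and the other 17 of 19 were kept. Both lost peaks were under the vehicle-list median area of 581.4, at 527.3 and 355.0. NOTUM had a peak within 1 kb of its end where the vehicle list had none, but that peak overlapped a vehicle peak and was not a gained peak. CCND1, the cyclin D1 gene, lost 3 of 4 peaks with 1.69 expected, and SP5 lost 2 of 2 with 0.58. MYC lost 2 of 12 and gained 4. Outside the naming rule, and chosen after their values were seen, ZNRF3 lost 8 of 14 peaks with 4.24 expected, NKD1 6 of 12 with 3.07, AXIN2 4 of 7 with 1.87, LEF1 3 of 4 with 1.15 and APCDD1 3 of 5 with 1.31.

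Steroidogenic genes kept 73 of 103 peaks with FSK (70.9%, 72.7% expected, percentile 35.93) and all 18 gene-end peaks, MC2R included. They gained 20 peaks, 21.3% of their 94 FSK peaks (14.2 to 30.6), at percentile 74.83 of random lists: 4 at SCARB1, 3 each at CYP11A1, PDE8A and CYP21A2, and 2 at NR5A1. CYP21A2, the steroid 21-hydroxylase gene, also gained a gene-end peak, which is uncertain because of its near-identical pseudogene. The cAMP targets kept 87 of 116 (75.0%, 74.9% expected, percentile 63.31) and gained 18 of 105 (17.1%, 11.1 to 25.5, percentile 62.21), with 4 at PDE4B and 2 each at SGK1, NFIL3 and PDE4D. PDE4D lost 7 of 10 vehicle peaks with 3.24 expected, and its gene-end peak and that of SGK1 were lost, as they were with both inhibitors.

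Gained peaks were scarce near developmental transcription factors, 11 of 157 FSK peaks (7.01%, 3.96 to 12.1, percentile 0.54), and near cell cycle genes, 1 of 52 (1.92%, 0.34 to 10.1, percentile 0.695), that peak lying near CCNE1. Neither share was adjusted for peak area or class, and 4.963% of FSK gains were gene-end peaks against 25.26% of all FSK peaks. Whether peak size or position accounts for the scarcity was not tested. Both gene lists kept vehicle peaks inside the range, 137 of 178 (percentile 95.99) and 51 of 63 (percentile 72.15). Among developmental transcription factors gene-end peaks were lost at GSC, LHX1 and HOXD10. Polycomb and coactivator genes kept 73 of 102 (percentile 24.48) and all 24 gene ends; JARID2 lost 6 of 13 peaks with 2.59 expected, and TCF7L2 gained 4. EZH2 and CREBBP kept 3 of 5 and 3 of 4, CTNNB1 2 of 3 and NR5A1 3 of 3. The p53 and stress list kept 47 of 58 (percentile 47.94), cholesterol supply genes 56 of 75 (percentile 69.57) and housekeeping genes 51 of 60 (percentile 97.11); by gene content as well, housekeeping genes were outside the range at 9.82 points (percentile 97.93), but by area alone the value was 0.123 in the larger-area 50% of both lists and 1.78 with lists of equal length. Among marker lists, fibroblast genes kept 27 of 43 (percentile 30.16), endothelial 17 of 28 (percentile 62.66), immune 39 of 46 (percentile 96.85) and chromaffin 15 of 25 (percentile 7.84).

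**Figure D4:**
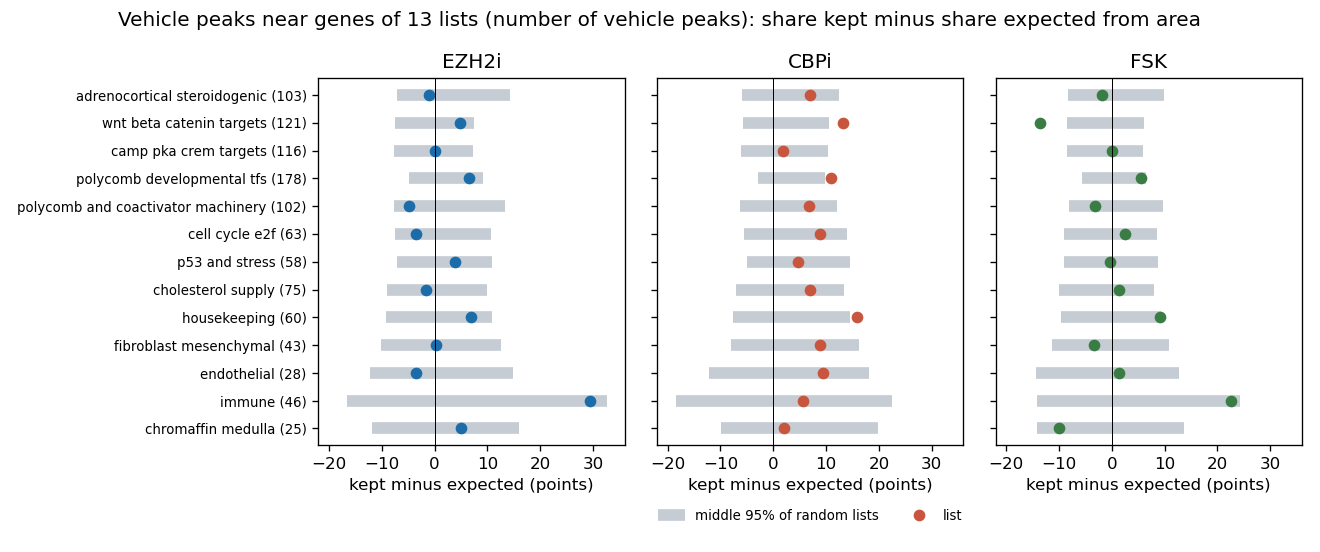
Each point is the share of a gene list's vehicle peaks kept minus the share expected from peak area (horizontal axis, points), with the list's number of vehicle peaks in its label, and grey bars span the middle 95% of 10000 random lists. Wnt targets lie above the bar with CBPi (13.3) and below it with FSK (-13.6).

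The treatments were then compared with one another. Of the vehicle peaks, 32083 were kept with all 3 treatments and 10900 were lost with all 3; 4845 were lost with EZH2i and CBPi alone, 3524 with EZH2i and FSK alone and 1016 with CBPi and FSK alone, while 3721 were lost only with EZH2i, 1912 only with CBPi and 3015 only with FSK. EZH2i and CBPi shared 15745 lost peaks, 2.24 times the 7035.7 of independent lists and 1.24 times the simulated mean of 12661 (SD 79.7 over 1000 simulations). EZH2i and FSK shared 14424, with 6953.6 from independent lists and 12447 simulated, and CBPi and FSK shared 11916, with 5647.9 and 10354. Part of each excess may come from the shared vehicle list. Of the 2867 peaks gained with EZH2i, 1145 overlapped a CBPi gain (39.94%, 38.16 to 41.74) and 1142 an FSK gain (39.83%, 38.06 to 41.64), and 1917 of the 5067 CBPi gains overlapped an FSK gain (37.83%, 36.51 to 39.18). Independent lists would share 281, 409 and 677 gains, and simulations at each list's own rate per area decile gave means of 296, 403 and 633. Of the 1195 EZH2i gains that lay on any CBPi peak, 1145 lay on a CBPi gain, because both are set against the same vehicle list, so part of these overlaps comes from that list. By shared base pairs the EZH2i and CBPi lists were nearest, with a Jaccard index of 0.671. The vehicle list reached 0.591 with EZH2i, 0.641 with CBPi and 0.605 with FSK, and FSK reached 0.627 with either inhibitor. This index depends on list length, and the vehicle list was the longest. With lists of equal length, a setting added after seeing the data, EZH2i and CBPi reached 0.682. The vehicle list then reached 0.639 (EZH2i), 0.67 (CBPi) and 0.631 (FSK), and FSK 0.638 with EZH2i and 0.634 with CBPi. Treated lists were then little nearer to each other than to the vehicle list.

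Differences between treatments in the share kept beyond expectation were placed among the same random lists. For Wnt targets the CBPi value exceeded the FSK value by 26.9 points (random range -6.26 to 13.5) and the EZH2i value exceeded it by 18.3 points (-7.7 to 9.75), both above all 10000 random lists. Cells had 48 h of FSK but 96 h of either inhibitor, so drug and exposure time cannot be told apart in differences from FSK. Polycomb and coactivator genes kept fewer peaks with EZH2i than with CBPi, by -11.6 points (-11.4 to 10.2, percentile 2.26), but in the larger-area 50% of both lists the difference turned to 1.82 points. These were the 3 of 39 differences outside the range. Among shares kept within a treatment 4 of 39 were outside it, and among gained shares 3 of 39. For shares kept, 7 to 10 of 100 unchanged simulated lists fell outside, so 4 of 39 is no clear excess over chance; for gained shares and differences that rate was not simulated. With expectation by gene content 5 of 39 differences were outside: the same 3, at 25.9, 18.2 and -11.5 points, cell cycle genes with EZH2i minus CBPi at -13.9 points (-11.3 to 8.47, percentile 0.77) and fibroblast genes with CBPi minus FSK at 17.2 points (percentile 97.61). By area alone these last 2 were inside the range, and in the larger-area 50% of both lists they were -2.93 and 0.837 points; with lists of equal length the cell cycle difference was -4.31.

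**Figure D5:**
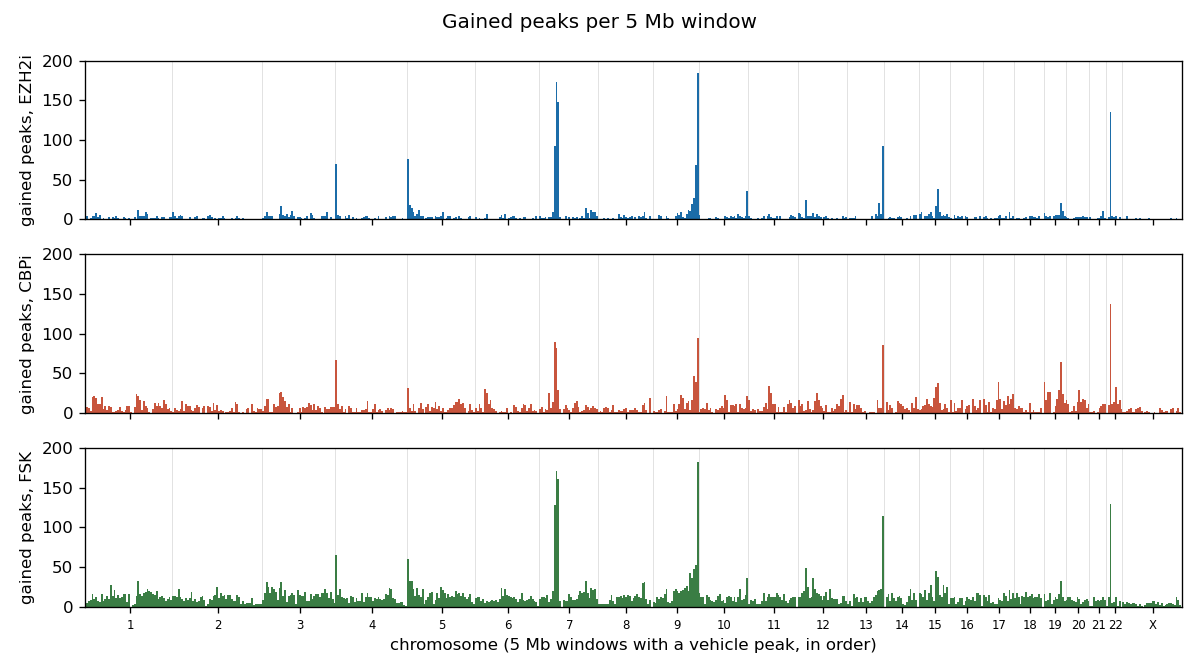
The number of gained peaks (vertical axis) in each 5 Mb window along chromosomes 1 to 22 and X (horizontal axis) is shown for EZH2i, CBPi and FSK in turn. Several windows stand out with each treatment, among them chromosome 7 at 45 to 50 Mb with 173, 82 and 171 gained peaks and chromosome 9 at 135 to 140 Mb with 185, 94 and 182, whereas chromosome 7 at 50 to 55 Mb held 148 with EZH2i and 161 with FSK but 29 with CBPi.

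Gained peaks were unevenly placed along the genome. Of 597 windows of 5 Mb, 6 were among the 10 with the most gained peaks for every treatment. They lay on chromosome 4 at 0 to 5 Mb, chromosome 7 at 40 to 45 and 45 to 50 Mb, chromosome 9 at 135 to 140 Mb, chromosome 13 at 110 to 115 Mb and chromosome 22 at 20 to 25 Mb. They held 26.1% of EZH2i gains (24.5 to 27.7), 11% of CBPi gains (10.1 to 11.9) and 9.75% of FSK gains (9.13 to 10.4), against 2.55% of vehicle peaks. With CBPi 3 windows tied at 39 gains for the last of the 10 places; with ties included, chromosome 9 at 130 to 135 Mb made 7 shared windows, holding 28.5%, 11.7% and 10.4% of gains. RASA3, TNS3, RAMP3, CAMK2B, LZTR1, C13orf46, DGKQ and EGFL7, named above for gains, lie in these windows, as do VWC2 and ABCA13, named for losses with CBPi. The window on chromosome 7 at 50 to 55 Mb, which holds COBL, IKZF1 and GRB10, was not among them: it had 148 gains with EZH2i and 161 with FSK, and with CBPi 29 gains and 203 losses.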

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

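Of 96 alternatives to the counts, differences and overlaps between treatments, 41 stayed close to the reported value and 55 moved. Only the gene-end minus distal differences were checked for a change of sign, and none changed. Counts and ratios could only stay or move. The order of treatments by lost peaks did change, from 22990 (EZH2i), 18673 (CBPi) and 18455 (FSK) to 7289, 7415 and 8501 with lists of equal length. Alternatives for gained peaks shared between treatments, for differences between treatments, for windows, for expectations by class or gene content and for assignment to the gene whose body holds the summit were chosen after seeing the data. The cause of each move was not tested, except that fewer peaks enter when lists are cut. With the larger-area 50% of both lists, lost peaks numbered 10812 (EZH2i), 8562 (CBPi) and 8183 (FSK) and gained peaks 827, 1751 and 3119; the gene-end minus distal difference was 40.4 points with EZH2i and 37.5 with CBPi; shared-loss ratios were 2.5 (EZH2i and CBPi), 2.29 (EZH2i and FSK) and 2.35 (CBPi and FSK), and shared gains 358, 341 and 631 in the same order of pairs. With lists of equal length, 7289, 7415 and 8501 peaks were lost and 6841 gained with EZH2i; differences were 21.1, 23 and 21.8 points, ratios 3.66, 2.82 and 2.62, and shared gains 3051 (EZH2i and CBPi) and 2403 (EZH2i and FSK). Lists of 1 length must lose and gain like numbers, so these counts say nothing of the excess of losses. With larger-area query peaks against whole lists, 2326, 1663 and 1803 were lost, 214, 243 and 941 gained, differences were 10.7, 8.16 and 7.76 points and ratios 8.27, 4.76 and 4.79. With 50% of the peak covered, differences were 39.2, 36.2 and 29.9 points and ratios 2.01, 1.85 and 1.89; with the summit covered the EZH2i and CBPi ratio was 2.22. A 2 kb gene-end window gave 33.5, 31.6 and 25.0 points, and matching on area decile 11.4, 17.9 and 4.9. Against simulations by decile the ratios were 1.24, 1.16 and 1.15. Without the 6 shared windows EZH2i and FSK shared 755 gains. Merging peaks within 500 bp moved no count by over 1.5 times, and using all sequences was void because no peak lay elsewhere.

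Of 312 alternatives for gene lists, 296 stayed within the interval of the share kept and 16 moved, and no share kept with a single treatment that was outside the random range by peak area changed sign. Fibroblast genes with CBPi, outside it only by gene content, went from 8.94 to -3.0 points in the larger-area 50% of both lists, and housekeeping genes with FSK from 9.06 to 0.123. Of 40 alternatives for 5 differences between treatments, 1 was reversed: for Polycomb and coactivator genes EZH2i minus CBPi was 1.82 points in the larger-area 50% of both lists against -11.6, and the cause was not tested. Over 8 alternatives Wnt targets ranged from -14.0 to -9.75 points with FSK and from 9.97 to 14.8 with CBPi, developmental transcription factors with CBPi from 0.424 to 11.9 and housekeeping genes with CBPi from 3.84 to 16.1. The motif alternatives were not run, since no genome sequence was used. Leaving out a replicate was not possible with 1 list per group, and no paired analysis was possible because the lists carry no replicate numbers. Read depth is unknown, so whether shorter lists reflect fewer reads cannot be seen in these files.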

Other observations

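Retention differed between chromosomes. With CBPi, 92.61% of vehicle peaks on chromosome 19 were kept (91.26 to 93.76), 88.72% on chromosome 22 (86.23 to 90.81) and 83.68% on chromosome 17 (81.96 to 85.26), against 59.71% on chromosome 4 (58.04 to 61.34) and 60.32% on chromosome 18 (57.58 to 63.0). Beyond what peak area predicted, chromosomes 19, 22 and 17 kept 15.7, 19.7 and 12.9 points more, and chromosomes 4 and 18 differed by -7.6 and -8.22 points. With FSK the corresponding shares on chromosomes 19, 22, 17, 4 and 18 were 84.27%, 74.86%, 73.44%, 67.61% and 70.64%. Beyond peak area these differed by 7.27, 5.51, 2.41, -0.123 and 1.65 points. With EZH2i the shares were 82.97%, 73.37%, 69.91%, 55.69% and 58.48%, which differed by 11.8, 11.6, 5.85, -4.1 and -2.77 points.

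Of the tests below, those on gene-dense windows, on peak class and on gene content for the Wnt list were set before their values were seen; the others were chosen after. For distal peaks, 2 tests set beforehand are not relied on: a difference of over 2 points within area deciles (11.4, 17.9 and 4.9 points with EZH2i, CBPi and FSK), and the same matched on summit height too (11.9, 18.1 and 5.78). Noise in vehicle areas may leave such differences even under an even loss, which was not simulated.

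Distal peaks were lost more often than gene-end peaks, and a loss of sensitivity alike in the treatments would give equal differences within area deciles of lists of equal length. With the treated lists shortened, CBPi exceeded FSK by 14.2 points (13.2 to 15.3) and EZH2i by 8.14, and EZH2i exceeded FSK by 6.08. With the vehicle list shortened too, these were 8.32 (7.07 to 9.38), 3.91 (2.91 to 4.83) and 4.41 (3.42 to 5.42). Without matching on area the differences lay close together at 21.1 (EZH2i), 23 (CBPi) and 21.8 (FSK). The matched differences were thus unequal, but their intervals cover counting error only, and each group is a single list. Variation between lists of the same group was not measured, and the effect of noise in vehicle areas was not simulated. The test therefore cannot decide whether a loss of sensitivity alike in the treatments was the whole cause. At equal area gene-end peaks were 27.4% of the lowest and 17.1% of the tallest of 5 height bins, while the tallest peaks were kept more often than the lowest by 11.1 (EZH2i), 4.69 (CBPi) and 11.9 (FSK) points, so height worked the other way, which argues against peak shape as the cause. Among distal peaks alone, the share kept in gene-rich minus gene-poor windows at equal area was 23.8 points with CBPi (22.9 to 24.8), 8.25 with EZH2i (7.35 to 9.29) and -2.65 with FSK (-3.68 to -1.53). A loss that follows regional base composition, in the libraries or in the cells, may therefore account for part of the CBPi and EZH2i patterns. The FSK value went the other way, against a loss that follows gene content over 5 Mb windows. Gene number only stands in for base composition, so base composition stays open for FSK too. GC content itself was not tested, and an effect of either inhibitor on gene-poor chromatin stays open as an untested biological explanation.

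Gained peaks crowded into 6 windows that were chosen as being in the top 10 of all 3 treatments, so that sharing says nothing of opening specific to one treatment, which stays open; chromosome 7 at 50 to 55 Mb, outside them, had 148 gains with EZH2i and 161 with FSK but 29 with CBPi. Inside these windows gained peaks were broad and shallow: their median area per base pair was at most 0.636 times that of gained peaks elsewhere. Vehicle peaks were also dense there, at a mean of 260 per window against 101. That mean was raised by the chromosome 7 windows, with 407 and 473, while the others held 146 to 208. Raised background over extra DNA copies may produce these gained peaks, but copy number was not measured here. Gene-dense sequence may contribute but stays open: 3 of the 6 windows were in the top 10% by gene number, just the share set beforehand as needed, and 3 of 7 with a tied window included, which is under it.

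Wnt targets lost peaks with FSK beyond expectation. Leaving out any 1 gene left at most -11.8 points (random range -8.5 to 6.09), so no single gene accounted for it. Taking expectation within gene-end and distal peaks gave -13.3 points, and within windows of like gene content -13.1, both below the random range. The 26.9 points between CBPi and FSK cannot decide on a loss of weak peaks common to the treatments. Expectation used each treatment's own share kept at equal area, so a loss set by peak area was already taken out. That difference also joins a CBPi excess of 13.3 points to the FSK value of -13.6. As a hypothesis, cAMP signalling may reduce accessibility near Wnt targets in these cells; it was found and tested on the same lists as 1 of 39 comparisons, GC content and library quality were not examined, and no replicate lists were used to test it.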
